A study of Bos taurus with 33 samples.

How the data were processed

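Whole blood of cows was profiled by enzymatic methyl sequencing, in which enzymes protect methylated and hydroxymethylated cytosines and then deaminate unmodified ones, so that unmodified cytosines read as thymine. The labels placed 33 libraries in the groups used here, 15 from control cows and 18 from cows recorded for low production. Replicates were numbered in accession order within each group, and these numbers named the libraries without pairing them. Another 63 columns of per-sample values in the table belonged to none of these libraries and were not used.

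The deposited table listed 81850 CpGs with the authors' correlation and q-value per CpG, an annotation, and the methylation of each library as a percent. Coordinates were on the build ARS-UCD1.2, and reads and annotations were handled with fastp 0.23.1, Bismark, DRAGEN and ChIPseeker 1.32.1, per the submitters' processing notes. The authors' correlation is a score between -1 and 1, and the file headers give neither the variable that was correlated nor the cows that entered it. The kind of coefficient, the way the authors' q-values were adjusted and any coverage minimum were not given in the sources used here. Every listed CpG had an absolute correlation of at least 0.5, and the largest q-value in the authors' deposited table was 0.01. The percent methylation per library was taken as deposited, with missing values left missing. The depth behind each percentage is unknown, so no interval from read counts was computed. The number of CpGs with a value per library, from 29266 to 74379, was the only measure of coverage.

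CpGs with a positive correlation are called gaining and those with a negative correlation losing, whatever variable the authors used. The share of gaining CpGs was given a 95% interval from 1000 bootstrap draws of 1 Mb windows, with 5 Mb windows as an alternative. Annotation classes were compared with all other CpGs by the same bootstrap, two-sided, with Benjamini-Hochberg adjustment over classes. The smallest p that these draws can give is 0.002. A CpG was assigned to a gene when it lay in it or within 10 kb of its start, which held for 28961 CpGs and 11568 genes. Density was expressed per Mb, and chromosome X was set against the 29 autosomes by exact permutation of the chromosome labels.

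There were 16 gene lists, fixed before the data were examined: age clock loci, homeobox and developmental transcription factors, neuronal receptors and channels, T cell, NK and cytotoxic, B cell, monocyte, neutrophil, erythroid and platelet, cytokine and inflammation, DNA methylation and Polycomb machinery, longevity and senescence, milk production and lactation, clustered protocadherins, imprinted genes, and a ribosome and housekeeping comparison list. Each was compared with 10000 random gene lists of the same size, matched on the number of listed CpGs per gene, with a two-sided p and adjustment over the lists. The coverage of the lists was counted without a test, because gene lengths on the build of the table were not used here. Gene symbols were taken from the table, and a gene table on ARS-UCD2.0 served for names alone. Of the 682 list genes, 639 had their symbol in it.

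Low production was compared with control per CpG with limma 3.58.1 in R 4.3.3, on M values, log2 of the methylated over the unmethylated fraction after adding 0.01 to both. A test of read counts would need the depth. At least 1 value in each group and 3 in all were required, which left 80789 CpGs, a lone library being assumed to vary like the other group, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Means per cow over gaining or losing CpGs, list means and gene means were compared by two-sided permutation tests with 100000 draws, for which 1e-05 is the smallest possible p, or by exact permutation tests where a group had fewer than 10 values. For classes, lists, genes and clusters each CpG was first centred on its mean over libraries, and intervals came from 10000 bootstrap draws of cows. Adjacent CpGs within 1 kb were joined into clusters, and clusters of at least 10 CpGs were described singly. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

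The genes named were chosen by a rule fixed before the data were examined, among genes whose symbol does not begin with LOC. It took the 5 most positive and the 5 most negative correlations, at most 1 CpG per gene, and the 5 genes with the most gaining and the 5 with the most losing promoter CpGs. It also took every age clock locus with a listed CpG, the 4 members of each other list with the most listed CpGs, and the 10 CpGs with the smallest limma p. Some genes that the rule takes are not reported here. The extreme correlations among CpGs with at least 30 values, the dense clusters, the chromosome 6 region and single list CpGs past the threshold were chosen after values were seen.

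The limma step was tested on simulated data over the same 80789 CpGs, with 100 CpGs of at least 2 values per group shifted by each of 3 sizes. It recovered 0% of shifts of 1 M unit, 18% of 2 and 61% of 4, and 5 of its 84 calls were false, at a median SD within groups of 1.84. The simulated M values were normal and independent between CpGs, and an SD of 0 was replaced by the median. These figures therefore do not cover calls in which all values of a group were equal. The list test called the planted list and none of the others, and the bootstrap interval covered a true promoter difference in 35 of 40 simulations. Alternatives changed the correlation and q thresholds, the counting of neighbouring CpGs, the promoter and distance definitions, the scale, the libraries, the minimum number of values and the adjustment for missing values. Islands of CpGs and their alternatives were not analysed here for lack of a genome of the build used, and dependence on age across cows was not tested because no ages were used.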

Results

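Methylation was measured in whole blood of 33 cows, 15 controls and 18 recorded for low production. The series title names age and disease, and the table analysed lists 81850 CpGs whose methylation correlated with a variable that its headers do not name. The libraries had values at 29266 to 74379 of these CpGs, with a median of 26.9% missing, and the depth per CpG is unknown. Control libraries lacked 34.9% ± 13.3 (SD, n = 15) of the CpGs and low production libraries 24.3% ± 11.6 (SD, n = 18), a difference past the permutation test (p = 0.0216).

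The first question was in which direction and where in the genome the listed CpGs lay. CpGs with a negative correlation in the authors' deposited table, called losing, outnumbered gaining ones by 54440 to 27410. Gaining CpGs made up 33.5% (95% interval 32.8 to 34.1). Promoters stood apart, with 54.9% of their 9730 CpGs gaining against 30.6% elsewhere, a difference of 24.3 percentage points (22.6 to 25.9). Distal intergenic CpGs, the largest class with 43314, gained in 26.9%. The share was 34.3% in introns, 49.1% in exons, 51.9% in 3' UTRs and 77.8% of the 18 CpGs in 5' UTRs. Each of these classes differed from the rest by the bootstrap over windows, with an adjusted p of 0.0303 for introns and of 0.0028, from the smallest p possible, for the others. The 106 downstream CpGs did not (39.6%, adjusted p = 0.190). The classes were not matched on methylation level, and a part for level was not tested.

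Within promoters the gaining share was 63.8% up to 1 kb from the start, 49.2% from 1 to 2 kb and 43.2% from 2 to 3 kb. CpGs beyond 10 kb gained in 28.7%, which was 35.1 percentage points below those within 1 kb (33.3 to 37.0, p = 0.002, the smallest possible). Among CpGs with a correlation of at least 0.7 in absolute size in the authors' deposited table, the promoter difference was 12.0 points (8.61 to 15.8) and the distance difference 19.7 (14.9 to 24.9). Among CpGs with at least 25 values they were 26.5 (24.4 to 28.7) and 38.9 (36.2 to 41.2).

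**Figure D1:**
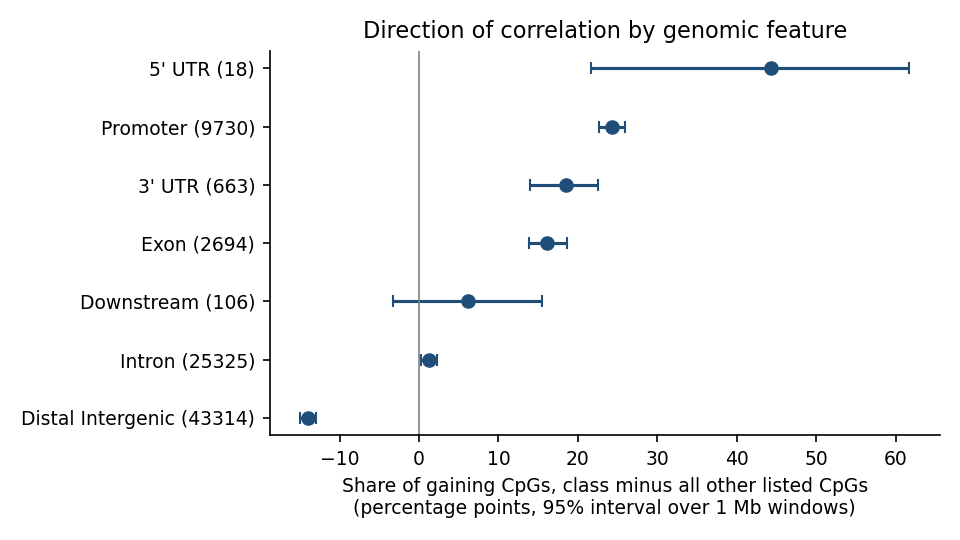
Share of gaining CpGs in each annotation class minus the share among all other listed CpGs, in percentage points (points), with 95% intervals over 1 Mb windows (bars) and the number of CpGs in brackets. Promoters lay 24.3 points above the rest and distal intergenic CpGs at -14.0.

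Promoter CpGs gained in groups at a few genes. MAB21L1, a developmental gene of the eye and nervous system, held 69 gaining and no losing promoter CpGs on chromosome 12. IRF2BPL followed with 48, then NSD1, a histone methyltransferase, with 22, the zinc finger gene ZNF414 with 20 and INKA2 with 19. Losing promoter CpGs were fewer per gene, at most 6, at HUWE1, a ubiquitin ligase gene on chromosome X. PADI2, FOXN3, LILRA4 and COBLL1 came next, with 5, 5, 5 and 4.

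The most positive correlations in the authors' deposited table were 1 in an intron of TMEM132D (chromosome 17, position 47546830), 0.991 in PLXDC1, 0.991 at the ASPG promoter, and 0.986 at the promoters of COBL and HOXA7. The most negative were -1 in introns of TNIP2, FRK and NT5E, -0.991 in CLSTN2 and -0.986 in ERBB4, per the authors' deposited table. These 10 CpGs had values in only 2 to 7 of the 33 libraries. Among CpGs with at least 30 values, the authors' deposited table gave the most positive correlation, 0.748, 8700 bp from the start of SKIDA1 (chromosome 13, position 22722425). NIBAN2 followed in the authors' deposited table at 0.73, then ZNF385B at 0.727, MAB21L1 at 0.698 and TMEM225B at 0.690. The most negative there were -0.735 and -0.721 in introns of the collagen genes COL5A1 and COL4A1, then -0.701 near UNC5B, -0.690 in PTPN3 and -0.686 near TEX35, per the authors' deposited table.

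Genes of homeobox and developmental transcription factors gained. Of their 604 listed CpGs, 497 were gaining (82.3%), against a median of 43.1% in random lists with a 95% range from 37.9 to 48.5 (adjusted p = 0.0032, from the smallest p possible). At their promoters 88.0% of 326 CpGs gained, against 65.5% in random lists. The random lists were not matched on methylation level. In controls the CpGs of this list averaged 20.4%, against 56.8% to 85.2% in the other lists. Whether level accounts for part of the gaining share was not tested. PAX6, a regulator of eye and brain development, had 12 of 14 CpGs gaining. NKX6-1 had 9 of 11, NR2F2 10 of 11 and SIM2 7 of 12. Among CpGs with at least 25 values the list stood at 84.75% (adjusted p = 0.0032). At absolute correlations of at least 0.7 in the authors' deposited table the list stood at 64.3% and was no longer past the threshold (adjusted p = 1).

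Age clock loci, genes whose methylation tracks age in other mammals, had 47 of 81 CpGs gaining (58.0%, adjusted p = 0.314). All listed CpGs gained at ELOVL2 (3), TRIL (3) and LHFPL4 (5), and 7 of 8 gained at EVX2. NEUROD1 had 5 of 6 gaining, SLC12A5 4 of 5, RASSF5 4 of 6, SFRP2 2 of 3, GRIA2 4 of 8 and FHL2 1 of 2. The lone CpGs at ZYG11A, HOXC4, PDE4C, CELF6, HSF4 and OTUD7A were gaining. Losing CpGs made up 6 of 7 at CCDC102B, 5 of 7 at TWIST2, all 3 at LHFPL3 and both at LARP1 and TFAP2D. TRIM59, PENK and ASPA each had 1 losing CpG.

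No other list passed the threshold in the share of gaining CpGs. Neuronal receptors and channels stood at 37.3% of 268 CpGs against 45.2% in random lists (adjusted p = 0.574), with 19 of 29 losing at DPP6, and 5 of 13 gaining at both KCND2 and CACNA1E. GRIK3 had 7 gaining and 7 losing. The adjusted p of the lists that follow was 0.914. Among blood cell markers, the gaining share was 39.8% for T cell, 45.3% for B cell, 47.8% for NK and cytotoxic, 46.4% for monocyte, 36.4% for neutrophil, and 47.8% for erythroid and platelet genes. It was 32.6% for cytokine and inflammation genes, 50% for the DNA methylation and Polycomb machinery, and 37.7% for longevity and senescence genes. Milk production and lactation genes stood at 39.2%, clustered protocadherins at 46.7%, imprinted genes at 45.1%, and the ribosome and housekeeping comparison list at 43.5%. When the share was averaged over genes, the T cell list stood at 19.5% and passed (adjusted p = 0.0272).

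Within these lists single genes went in different directions. Of the T cell genes, GATA3 had 12 of 15 CpGs gaining and ZAP70 8 of 10, while CAMK4 had 6 of 7 losing and BCL11B 5 of 8 losing. At the gene of the pore-forming protein perforin, PRF1, all 5 CpGs were losing, whereas all 4 at EOMES, 5 of 8 at RUNX3 and 1 of 2 at IL2RB were gaining. DNMT3A, a de novo DNA methyltransferase gene, had 11 of 13 gaining, against 2 of 7 at JARID2 and 2 of 4 at TET3 and ASXL1. At VCAN 3 of 7 gained and at KLF4 2 of 3, and both CEBPB CpGs were losing. The B cell genes EBF1, PAX5, BCL11A and SPIB had 5 of 14, 4 of 7, 3 of 6 and 4 of 5 gaining. Altogether 428 of the 682 list genes had a listed CpG, and 10441 of 21666 protein-coding symbols (48.2%) did.

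**Figure D2:**
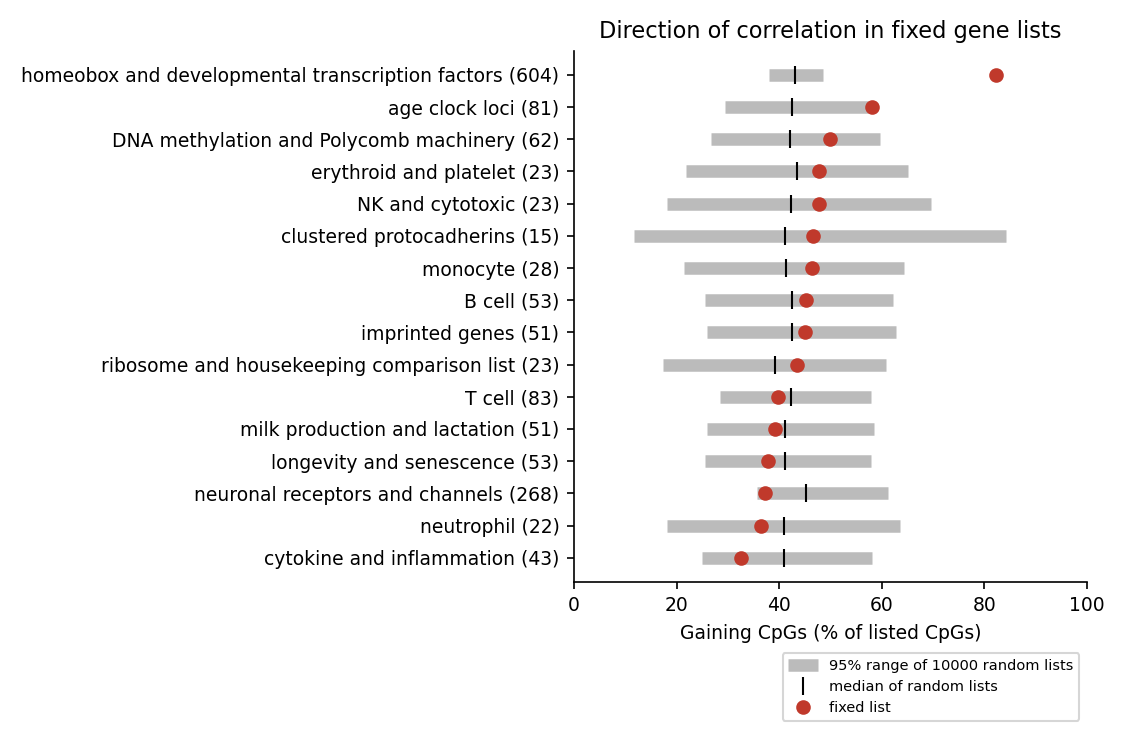
Share of gaining CpGs, in percent, in each fixed gene list (points), with the median and 95% range of 10000 random lists matched on CpGs per gene. Numbers in brackets are CpGs, and homeobox and developmental transcription factors, at 82.3%, lay outside their range.

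Chromosome X held 21.7 listed CpGs per Mb against 32.6 ± 6.09 (SD, n = 29) over the autosomes, a difference that did not pass the exact permutation test (p = 0.133, the smallest possible being 0.0333). All 13 mitochondrial CpGs were losing, at a very low level, with cow means from 0.418% to 1.82%. The 1 Mb window with the most listed CpGs lay on chromosome 6 from 5000001 to 6000000, with 281 CpGs against a median of 25, and 17.1% of them gained. From 4.5 to 6.8 Mb on this chromosome 132 CpGs were gaining and 336 losing. SEC24D, a gene of the secretory pathway coat, held 29, PDE5A 18, METTL14, of the RNA methyltransferase complex, 17, and FABP2 8. Over this region cow means ran from 14.3% to 82.5% at gaining and from 20.5% to 86.3% at losing CpGs. Low production minus control was 9.62 points (-3.15 to 22.3) at gaining and -10.2 (-21.9 to 1.88) at losing CpGs there. With this spread neither passed the permutation test (p = 0.166 and 0.123). Of the 18 low production cows, 13 lay above the control median at gaining and 15 below it at losing CpGs.

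**Figure D3:**
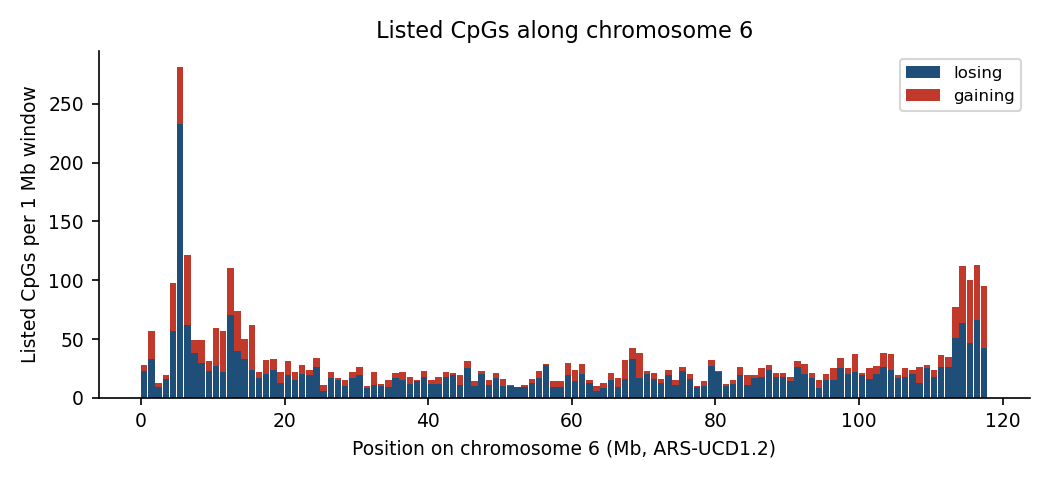
Number of listed CpGs per 1 Mb window along chromosome 6 (position in Mb on ARS-UCD1.2), with losing and gaining CpGs stacked. The window from 5000001 to 6000000 held 281 CpGs, 48 of them gaining.

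The second question was whether cows of low production differed from controls at the listed CpGs. They stood higher at gaining CpGs, with 66.7% ± 2.22 (SD, n = 18) against 60.1% ± 2.28 (SD, n = 15), a difference of 6.59 points (5.05 to 8.02). At losing CpGs they stood lower, with 80.7% ± 1.46 (SD, n = 18) against 86.3% ± 1.61 (SD, n = 15), a difference of -5.65 (-6.65 to -4.59). All 18 low production cows lay above the control median at gaining and below it at losing CpGs. Both differences had the smallest permutation p possible, 1e-05. The CpGs were listed by the authors for a correlation that may rest in part on these cows, so the differences are not independent evidence of the groups' direction.

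Both differences kept their sign when libraries were split by their share of missing CpGs, although coverage still differed within the parts. With under 30% of CpGs missing, the 13 low production and 7 control libraries differed by 7.36 points at gaining and -6.46 at losing CpGs (exact permutation p = 3.87e-05 and 1.29e-05), and lacked 18.3% ± 4.91 (SD, n = 13) and 23.8% ± 5.89 (SD, n = 7). With at least 30% missing, 5 against 8 differed by 4.16 and -4.01 (exact permutation p = 0.00544 and 0.000777), and lacked 40% ± 8.80 (SD, n = 5) and 44.5% ± 9.77 (SD, n = 8). With the share of missing CpGs as a covariate, and each CpG centred on its mean over libraries, the differences over all libraries were 5.44 and -5.28. Without the covariate such centred means differed by 6.42 and -5.43. Within low production the mean at gaining CpGs, each centred on its mean over libraries, fell as more CpGs were missing, with Pearson r = -0.820 (adjusted permutation p = 0.00028) and Spearman rho = -0.785 (adjusted p = 0.00084) over 18 cows and 4 such relations. Without the 2 cows farthest from the median r was -0.753. In controls r was -0.359 (adjusted p = 0.249), rho -0.214 (adjusted p = 0.508) and, without the 2 farthest, r was -9.03e-05. At losing CpGs r was 0.370 in low production and -0.0898 in controls (adjusted p = 0.249 and 0.748), rho was 0.459 and -0.186 (adjusted p = 0.114 and 0.508), and without the 2 farthest r was 0.312 and -0.376.

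**Figure D4:**
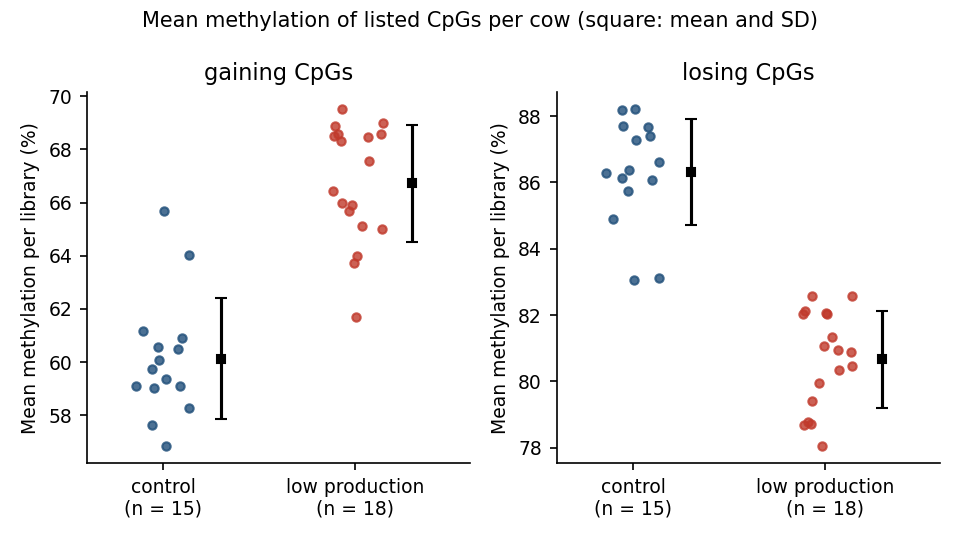
Mean methylation of each cow (circles), in percent, over gaining and over losing CpGs, by group, with the group mean (square) and SD (bar) on axes that do not start at 0. Low production cows averaged 66.7% against 60.1% at gaining and 80.7% against 86.3% at losing CpGs.

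Promoters, exons, introns, 3' UTRs and intergenic CpGs moved in these directions. At promoters low production cows stood at 40% ± 1.69 (SD, n = 18) against 35.3% ± 1.6 (SD, n = 15) over gaining CpGs, and at 73.8% ± 1.04 against 79.1% ± 1.59 over losing ones. Intergenic gaining CpGs differed by 7.26 points, intronic by 6.50, exonic by 5.83 and those of 3' UTRs by 6.29. Intergenic losing CpGs differed by -5.67, intronic by -5.10, exonic by -4.30 and those of 3' UTRs by -5.14. On chromosome X the differences were 7.88 and -5.49. Each had an adjusted permutation p of 1.11e-05, from the smallest p possible.

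Gaining CpGs packed in dense clusters showed no such difference. Over 533 gaining CpGs in clusters of at least 10, the means were 24.2% ± 6.37 (SD, n = 18) in low production and 25.4% ± 4.44 (SD, n = 15) in controls, a difference of -1.19 (-4.76 to 2.53, p = 0.544). Lone gaining CpGs differed by 6.77 (5.37 to 8.06) and those in clusters of 2 to 9 by 6.12 (4.66 to 7.53). There were 28 such clusters with 602 CpGs, of which 22 held gaining CpGs alone, and 14 of these 22 stood lower in low production. None passed the permutation test after adjustment over the 28. The largest had 96 gaining CpGs in an intron of ESPN (chromosome 16, 46913092 to 46914560), an actin-bundling protein gene of the inner ear, at 14.0% ± 8.85 (SD, n = 18) against 17.7% ± 5.38 (SD, n = 15). MAB21L1 held 3 clusters of 55, 28 and 14, and SKIDA1, DLG4 and ZNF503 held 23, 21 and 19. The IRF2BPL promoter cluster of 48 differed by -7.60 (adjusted p = 0.0619), against its gaining direction. Among the gaining clusters that stood higher, those at MIR3154, FPGS and ZNF414 differed by 12.1, 8.86 and 8.08 (adjusted p = 0.119, 0.427 and 0.427). The MEIS1 cluster of 23 losing CpGs differed by 5.27 (adjusted p = 0.427).

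**Figure D5:**
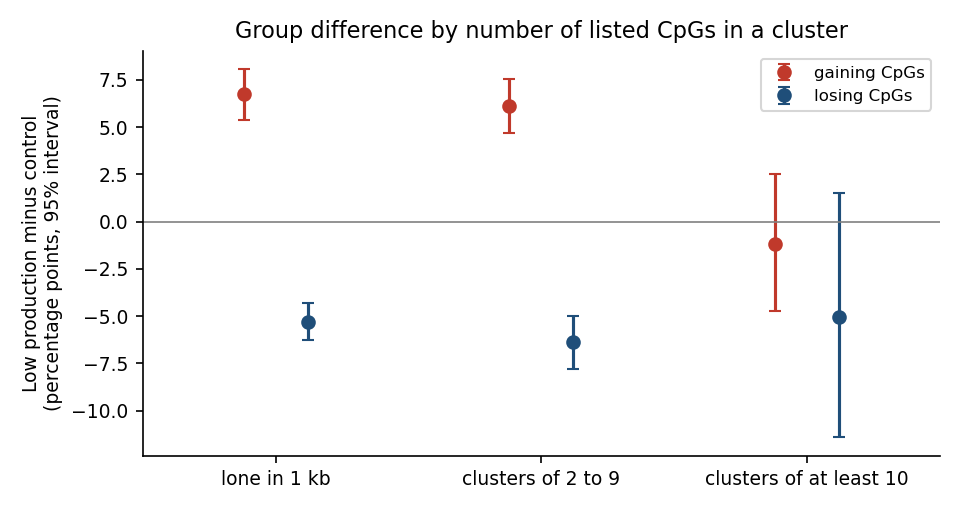
Low production minus control mean methylation, in percentage points with 95% intervals from bootstrap draws of cows, over gaining and over losing CpGs by the number of listed CpGs in their cluster. The interval of gaining CpGs in clusters of at least 10, from -4.76 to 2.53, lay below those of lone gaining CpGs and of clusters of 2 to 9.

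Per CpG, limma called 1479 of 80789 at an adjusted p under 0.05, 601 higher and 878 lower in low production, so that 40.6% of calls were higher. Of the calls 1478 had the sign of the authors' correlation, as had 89.4% of all CpGs tested, and 11 had a value from 1 library alone in a group. On beta values 388 were called, 54.6% higher. The median difference over CpGs was -0.46 M units, and with each library centred on its median it was -0.27, with 1297 called, 64.4% of them higher. Without low production 1 and control 11, the cows farthest from their groups' medians, 975 were called. With the share of missing CpGs as a covariate 312 were called, 289 of them among the 1479.

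The smallest limma p was at an intronic CpG of PRKDC, the DNA repair kinase gene (chromosome 14, position 19546227), with 99.5% ± 2.06 (SD, n = 14) in low production and 87.9% ± 3.80 (SD, n = 9) in controls (limma adjusted p = 2.25e-05). CpGs nearest CAPG, an actin-capping protein gene, and GLP1R, the receptor of an incretin hormone, were higher by 13.2 and 15.4 points. Those nearest MIR2377 and MRLN stood at 100% in all low production libraries with a value, 15.5 and 13.3 points above controls. Controls with a value were all at 100% at CpGs nearest CNTN4, NOBOX, ADAMTSL2 and RBM47, where low production differed by -13.4, -21.1, -17.5 and -8.27 points. The CpG nearest STRBP differed by -11.1. The 9 names after PRKDC give the nearest annotated gene, and of these only CAPG's CpG lay within 10 kb of the start. The ADAMTSL2 and RBM47 CpGs lay in introns of these genes, and those nearest NOBOX and GLP1R in introns of other annotated genes. Distances were -26052 bp for STRBP and -630446 bp for CNTN4, both in distal intergenic sequence. These 9 had limma adjusted p between 2.25e-05 and 0.00157, and NOBOX was not called on beta values (adjusted p = 0.0782). The spread of a group with all values at 100% rests on limma's pooled estimate, with 4 to 13 libraries in such groups.

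Homeobox and developmental transcription factors rose by 3.06 points in low production (2.11 to 4.04, adjusted p = 0.00016), to 23.5% ± 1.61 (SD, n = 18) from 20.4% ± 1.26 (SD, n = 15). The mix of gaining and losing CpGs in this list alone would give 4.32. Of their 596 tested CpGs limma called 10, and 1 when adjusted over the list alone, at the SALL3 promoter, a zinc finger gene, with 12.3% ± 9.55 (SD, n = 15) against 0.769% ± 2.77 (SD, n = 13). Others higher in low production were at OLIG2, HOXD11, BARX1, NKX2-2, NKX2-5, NR2F2 and FOXA1, by 5.71 to 20.1 points. FOXL2, a gene of ovary development, stood lower, with a difference of -7.99. Over its 11 CpGs NR2F2 rose by 7.35 (adjusted p = 0.0428). Without low production 1 and control 11 the difference was 7.34 (adjusted p = 0.0639).

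Neuronal receptors and channels stood lower, by a difference of -1.36 points (adjusted p = 0.0212) where their mix of gaining and losing CpGs alone would give -1.01, with 2 CpGs higher and 4 lower over all CpGs and also when adjusted over the list alone. GRIA2, a glutamate receptor gene, was higher at its promoter by 7.88 points and GRIN2B by 11.9, and DLGAP1, SCN2A, CACNA1B and GRM5 were lower, with differences of -21.6, -7.57, -5.81 and -8.58. With each library centred on its median over the listed CpGs, neuronal receptors and channels differed by 0.0727 (adjusted p = 0.835). Most listed CpGs were losing and stood lower in low production, so centring took out part of the group difference and moved every list upwards. Homeobox and developmental transcription factors went from 3.06 to 4.495 (adjusted p = 0.00016). The direction of the neuronal list thus rests on the scaling. T cell genes differed by -1.70 (adjusted p = 0.0214), against -0.718 from their mix, with CD28 higher and CD247 lower by limma, and 6 called when adjusted over the list alone, LEF1, ZAP70, CD27 and SATB1 besides. Milk production and lactation genes differed by -2.04 (adjusted p = 0.0494), against -0.782 from their mix, with no CpG called, also when adjusted over the list alone. No list was tested against the value from its mix. Neither of the last 2 lists passed with centred libraries, at -0.262 and -0.599 (both adjusted p = 0.744), nor did the last with under 30% of CpGs missing, at -1.17 (adjusted p = 0.367).

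The other lists did not pass, with adjusted p from 0.0653 to 0.646 and differences of 0.576 for age clock loci, -2.18 for NK and cytotoxic, -0.219 for B cell, -1.06 for monocyte, -1.02 for neutrophil, and -0.816 for erythroid and platelet genes. Cytokine and inflammation genes differed by -0.632, the DNA methylation and Polycomb machinery by 1.39 (adjusted p = 0.0653), longevity and senescence genes by -1.63 (adjusted p = 0.0862), clustered protocadherins by 2.06, imprinted genes by -0.840, and the ribosome and housekeeping comparison list by -0.674. Single CpGs called over all CpGs lay, among others, at DNMT3A and JARID2, higher by 16.6 and 8.43, and SPIB, higher by 22.2 with 2 control and 5 low production libraries. ITGA2B, a gene of platelets and their precursors, differed by -13.6, GRB10, an imprinted adaptor gene, by -16.1 and FOXO4 by -21.1. Adjusted over the list alone, the calls were 1 for age clock loci, at GRIA2, 3 for B cell, 2 for erythroid and platelet, 6 for cytokine and inflammation, of which the IL10RA call rests on 1 low production library against 4 controls, 3 for DNA methylation and Polycomb machinery, 1 for longevity and senescence and 1 for imprinted genes. They were 0 for NK and cytotoxic, monocyte, neutrophil, protocadherin and housekeeping genes.

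Of the named genes, 8 passed the test over their listed CpGs, NR2F2 among them. The test was against no difference, whereas all gaining CpGs, centred alike, differed by 6.42 and all losing ones by -5.43. No gene was tested against such values. Losing CpGs made up all at PRF1, NT5E and LHFPL3 and 11 of 12 at ERBB4. Gaining CpGs made up 10 of 11 at NR2F2, 3 of 4 at TGFBR2 and 4 of 5 at ZIM2. IRF2BPL, with 49 gaining and no losing CpGs, differed against its direction. PRF1 stood at 77.6% ± 9.98 (SD, n = 18) against 89.9% ± 6.70 (SD, n = 15), a difference of -12.3 (adjusted permutation p = 0.0194). TGFBR2, a receptor gene of TGF-beta, rose by 5.22 points to 94.4% ± 2.60 (SD, n = 17) (adjusted p = 0.0194), and ZIM2, an imprinted gene, by 11.5 (adjusted p = 0.0476). ERBB4, NT5E, IRF2BPL and LHFPL3 differed by -6.02, -6.83, -7.31 and -9.04 (adjusted p = 0.0428 for the first and 0.0476 for the others). In libraries with under 30% of CpGs missing, TGFBR2 passed (adjusted p = 0.00526), and the other 6 of these and NR2F2 did not, with adjusted p from 0.0605 to 0.527 over fewer cows. There NR2F2, PRF1, ZIM2 and NT5E differed by 8.96, -13.6, 12.7 and -8.31, further from 0 than over all cows, and ERBB4, IRF2BPL and LHFPL3 by -4.21, -2.82 and -4.34, nearer to it. Without low production 1 and control 11, NT5E, LHFPL3 and ZIM2 did not pass (adjusted p = 0.0785), with differences of -6.59, -8.83 and 11.3. ERBB4, NT5E, IRF2BPL and LHFPL3 also did not pass with centred libraries (adjusted p = 0.0864 for the first and 0.0994 for the others), with differences of -4.55, -5.39, -5.88 and -7.55. Centring moved these differences upwards, as it did those of the lists.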

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

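Alternatives with a minimum number of values or a value in all libraries, 1 CpG per cluster for cow means, libraries chosen by missing CpGs, a covariate or centring were chosen after the data were seen, and all others were planned. The share of gaining CpGs was 41.1% at absolute correlations of at least 0.6, 44.8% at 0.7, 50% of 8 CpGs at q under 0.0001, 31.3% with 1 CpG per 1 kb cluster and 28.3% with at least 25 values. The promoter and distance differences kept their sign and threshold wherever they were computed. Past the threshold were 0 lists at 0.7 and 2 by the mean over genes, against 1. List genes with a CpG numbered 187 at 0.6, 93 at 0.7, 0 at q under 0.0001, 204 with at least 3 CpGs and 265 by promoters, which follows from fewer CpGs. Calls between the groups numbered 388 on beta values, 975 without low production 1 and control 11, 564 with under 30% missing, 89 of the 1518 CpGs with a value in all libraries and 312 with the covariate. For 975, 564 and 89 fewer libraries or CpGs entered, and the cause was not tested. Of 213 values for single lists, genes and CpGs, 191 stayed on the same side of the threshold, 20 lost the call, 1 gained it and 1 reversed, the neuronal list at 0.0727 with centred libraries. Of the 191, 125 were list shares and 26 of these crossed 50%, such as the neuronal list at 62.8% and neutrophil genes at 75% with 0.6. The causes were not tested. No test was run by CpG island or of age across cows, and no density per 1000 CpGs, and at q under 0.0001 only overall direction and coverage were computed. The unknown depth per CpG limits every percentage. No paired analysis was possible because replicate numbers follow accession order.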

Other observations

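Of the tests here, the comparison at matched methylation levels and that of strong with weak correlations were fixed before their results were seen, and the others were chosen afterwards.

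In some regions the listed CpGs varied together across cows more than in other windows. After each library's genome-wide score was removed, the mean correlation between CpGs of a 1 Mb window was 0.711 over the first window of chromosome 17, the highest of 371 windows. It was 0.441 from 4000001 to 5000000 on chromosome 6 and 0.354 from 46000001 to 47000000 on chromosome 16, where the ESPN cluster lies, against a median of 0.00434. In the chromosome 16 window the correlation was 0.0189 between CpGs at least 50 kb apart, against 0.320 in that of chromosome 17. Among the clusters, PRR15 held 12 losing CpGs in an intron, with cow means from 38.0% to 97.8%.

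Among annotation classes with called CpGs, downstream CpGs had 6 called of 106 (5.66%), 3' UTRs 18 of 654 (2.75%), exons 72 called of 2670 (2.70%), introns 466 of 25055 (1.86%), distal intergenic CpGs 755 of 42697 (1.77%) and promoters 162 of 9589 (1.69%), and the classes were not tested against each other. In exons 41 were higher in low production and 31 lower, and in distal intergenic CpGs 252 and 503. In clusters of at least 10 CpGs limma called 1 of 597, against 1253 of 65746 lone CpGs. Mitochondrial CpGs averaged 0.835% ± 0.378 (SD, n = 18) in low production and 1.02% ± 0.221 (SD, n = 15) in controls (permutation p = 0.0983).

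Low production cows stood higher at gaining and lower at losing CpGs. Only the real grouping, 1 of 100 splits of the 33 libraries, called as many CpGs, 1479 against at most 13 in other splits. Over the CpGs as listed, the real grouping thus stood apart from random ones. The splits did not repeat the authors' choice of CpGs, whose part stays open. That choice may rest on these cows, so the splits cannot tell whether the difference arose by chance. With missing CpGs as a covariate both differences had a permutation p of 1e-05, the smallest possible, against missing values as the whole cause. The covariate took 1 slope for both groups. At gaining CpGs r was -0.820 in low production and -0.359 in controls, so 1 slope may not hold there. Unequal conversion alone would move gaining and losing CpGs of one level together. At mean levels of 70 to 90% their group differences were 7.73 and -6.10, which lay 13.8 points apart (permutation p = 1e-05). The classes follow the sign of a correlation that may rest on these cows, so the split itself could set them apart. A part for conversion therefore stays open. A candidate explanation is that the correlated variable, which could be age, itself differed between the groups. Among CpGs with at least 25 values the group difference in the direction of the correlation was scaled by each CpG's spread. It was larger by 0.114 at absolute correlations of at least 0.65 than at 0.5 to 0.55 (permutation p = 0.00032). If the authors' correlation rests on these cows, such a rise follows from the choice of CpGs, so it cannot decide the question. In dense clusters the scaled difference of gaining CpGs differed from that of lone gaining CpGs by -0.676 (permutation p = 4e-05). That test was chosen after the gap had been seen in the same cows, and 96 of the 533 clustered CpGs lay at ESPN. The difference at lone CpGs may come from the authors' choice of CpGs, so the test cannot decide whether the correlated variable differed between the groups. Age, blood cell makeup, batch and production itself stay open, because no ages, cell counts or batches were used.

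The most extreme correlations sat at CpGs with few values among the 33 libraries. Of CpGs with absolute correlations of 0.5 to 0.55, 75.8% had at least 25 values, and the share was 60.2%, 28.4% and 1.5% in the next steps and 0% at 0.8 or more. This is consistent with a filter on q that admits CpGs with few values only at extreme correlations. However, 21 listed CpGs had no value in any of the 33 libraries, so values from outside these libraries entered the authors' correlation at least there. The number of values counted here need not be the number behind a correlation. Absolute correlations of 1 at TMEM132D, TNIP2, FRK and NT5E may still reflect few cows, and no biological explanation was tested.

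The window from 5000001 to 6000000 on chromosome 6 held 281 listed CpGs, more than any other. Correlations were computed for 60 of these CpGs, and 371 of 2640 windows entered. After removal of the genome-wide scores the CpGs correlated at 0.393 on average, rank 3 of 371, against a 95th percentile of 0.115 in other windows. Between CpGs at least 50 kb apart the correlation was 0.350, rank 1. A variable that moved all listed CpGs alike would leave no such excess, so these values argue against it as the whole cause. One that acted more strongly in this region could leave an excess and stays open. Cows that differ in sequence over this region could also give such values, a hypothesis that was not tested on genotypes.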
